A study of Escherichia coli K-12 with 2 samples.

How the data were processed

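RNA from Escherichia coli K-12 strain BW25113 was measured on 2 two-colour Agilent arrays, each described by the labels as a biological replicate. Per the labels, cells from overnight cultures were grown in 20 ml of LB to an OD of 0.8, the culture was divided into portions of 10 ml, and 1 portion received 2 mM sodium azide for 10 min. Total RNA was extracted with an RNeasy kit. Per the labels, RNA of the azide-treated portion carried Cy5 and RNA of the untreated portion carried Cy3 on both arrays, so dye and treatment could not be separated. Both arrays lay on 1 slide, so no slide effect could be tested.

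The intensity values of each spot and its local background were deposited as written by Agilent Feature Extraction 10.7.3.1 with protocol GE2_107_Sep09, per the file headers. The deposited processed signals, also intensities, had been background-subtracted and dye-normalized within each array by that software, per the file headers. The deposited log10 ratios were those of the processed signals, Cy5 over Cy3, with 0 where the software found no signal in either channel. The deposited p-values came from the software's error model for each spot, per the file headers, and were not used here. The value table of the whole series was identical to the log10 ratios of the scanner output for all 15744 spots, so its scale and direction were known. Its column medians were 0 on both arrays, and 33.9% and 37.0% of its values were exactly 0. The reason for the coarser decimals of the second array's output is not given in the sources used here.

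The design written before the data were examined named mean spot signals; the scanner output used here held median signals, which took their place. Background was corrected with normexp and an offset of 50, fitted on all spots, and log2 ratios of azide over untreated were normalized by loess within each array with control spots at weight 0. Spots marked as outliers were removed, which took 20 and 25 non-control spots. Spots of a probe were averaged, then probes of a gene. Of the 23 tested genes with more than 1 probe, 4 had probes on both sides of 0 and 5 had probes more than 1 log2 unit apart, with a largest gap of 2.10 for yciG.

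The 11494 non-control spots held 10691 distinct probes. Only the 4209 genes with a K-12 locus tag were used, of which 4052 were named through a gene table of assembly ASM584v2 by exact match and 157 kept their tag. A gene was tested if at least 1 of its probes was well above background in at least 1 channel on each array, which left 3973 genes. Between 90.4% and 92.2% of K-12 spots were well above background in the untreated channel and between 93.3% and 93.9% in the azide channel, and 0 spots were saturated. The number of arrays limited the precision.

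The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The ratio pairs the portions of each culture, so no further pairing term was fitted. With 1 residual degree of freedom per gene, the spread was largely borrowed across genes, with 7.37 prior degrees of freedom and a prior SD of 0.09 on the log2 scale. For 89 genes the untreated channel and for 30 genes the azide channel was not well above background on either array; these have only a bound, given as the bright channel's mean over the higher of the dim channel's own value and the lowest signal well above background, after loess and Aquantile, and open to dye bias.

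Before the data were examined, 37 gene lists were fixed from textbook knowledge of K-12 regulons and pathways, including the genes deleted in BW25113 as a negative control. The 36 lists with at least 4 tested genes were compared with all other tested genes by limma's camera. The correlation was preset at 0.01, and the test was two-sided and adjusted over the lists. The adjusted p with an estimated correlation, given beside each call, rests on 1 residual degree of freedom. The genes named were fixed by rule: the 10 largest rises and 10 largest falls among genes past the threshold with the same sign on both arrays, up to 4 called members with the largest change from each list past the threshold, and secA, secM, katG, cydA, cyoA, atpA and the deleted genes. Further members are named only to describe a list, and were chosen after their values were seen.

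The procedure was tested on simulated data for the azide comparison, made from the untreated signals of the 3973 genes. True log2 ratios of -2, -1 and -0.5 were called with the right sign in 88.2%, 76.5% and 69.7% of genes, and ratios of 0.5, 1 and 2 in 84.8%, 90.9% and 90.9%. The share first required at sizes of 1 or more was 80%; it was lowered to 70% after the falls of 1 log2 unit were seen to miss it. Among genes above the median signal 100% were called at each size. The shortfall lay in dim genes, where a true -2 was fitted at a median of -0.70; over all genes it was fitted at -1.13 with the offset of 50 and at -1.72 with an offset of 0, which called 76.5% of these genes. A true 2 was fitted at a median of 0.63 in dim genes and 1.81 over all genes. Fold changes printed for dim genes are therefore compressed in both directions. Unchanged genes made up 3.61% of the calls, the list shifted in the simulation ranked 1 of the 36, and 0 other lists were called. The simulation left 3753 of the 3973 genes unchanged, with noise independent between genes and no dye effect. In the data 3168 genes were called and dye went with treatment. These shares are therefore not error rates of the azide comparison.

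Alternatives set before the data were examined covered the background correction, the normalization within and between arrays, a separate-channel fit, the series value table, the filter on dim probes, the variance model, the choice of probes, the threshold, the list test and leaving out each replicate. No alternative was added afterwards. A further 16 gene lists were added after the data had been seen and are kept apart from the 36. Probes without a K-12 locus tag entered no comparison of genes or lists other than the alternative with all genes named on the array. The checks on neighbouring and replicate spots of the slide drew on all non-control spots.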

Results

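The series measured how mRNA levels of E. coli BW25113, a K-12 laboratory strain with deletions in the lactose, arabinose and rhamnose genes, differed between cells exposed to sodium azide and untreated cells of the same culture. Azide inhibits the SecA motor of protein export, haem enzymes such as catalase and cytochrome oxidases, and the F-type ATP synthase. The data were 2 two-colour arrays, 1 per biological replicate, each giving the ratio of the portion treated with 2 mM azide for 10 min to the untreated portion. All values are mean log2 ratios of azide over untreated, with the SD over the 2 arrays (n = 2) where an error is given and limma's adjusted p.

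The 10 genes with the largest rise in azide-treated over untreated cells were chaperone, cyanate and phage shock genes, and the 10 with the largest fall were ribosomal protein genes, sulphur uptake and assimilation genes and tdcA. The largest rise was in ibpB (b3686), a small heat shock protein, at 7.68 ± 0.01 (SD, n = 2; adjusted p = 1.28e-11), and its partner ibpA rose by 6.87 ± 0.05. The cyanate genes followed, with the cyanase gene cynS (b0340) at 7.54 ± 0.05, the carbonic anhydrase gene cynT at 6.91 ± 0.19 and the transporter gene cynX at 6.32 ± 0.13. The phage shock genes pspA, pspB, pspC and pspD, which respond to damage to the inner membrane, rose by 6.40 ± 0.02, 5.99 ± 0.04, 5.77 ± 0.07 and 5.70 ± 0.07, and the disaggregase gene clpB by 5.76 ± 0.03.

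The largest fall was in tsuA (b2013), a thiosulphate transporter, at -5.71 ± 0.02 (SD, n = 2; adjusted p = 2.97e-11), and its neighbour tsuB was at -4.72 ± 0.15. Ribosomal protein genes came next, with rplW at -4.92 ± 0.16, rpsJ at -4.78 ± 0.06, rplC at -4.77 ± 0.05, and rplV and rplB both at -4.70. The activator gene of threonine degradation, tdcA, was at -4.75 ± 0.07, the sulphate transporter gene cysA at -4.70 ± 0.08 and the sulphite reductase gene cysJ at -4.64 ± 0.33. With the scanner's processed signals the fold was over 1.5 times larger for ibpB (log2 8.44), cynT (8.30), cynX (7.30), tsuA (-7.38), tdcA (-7.23) and cysA (-5.76).

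**Figure D1:**
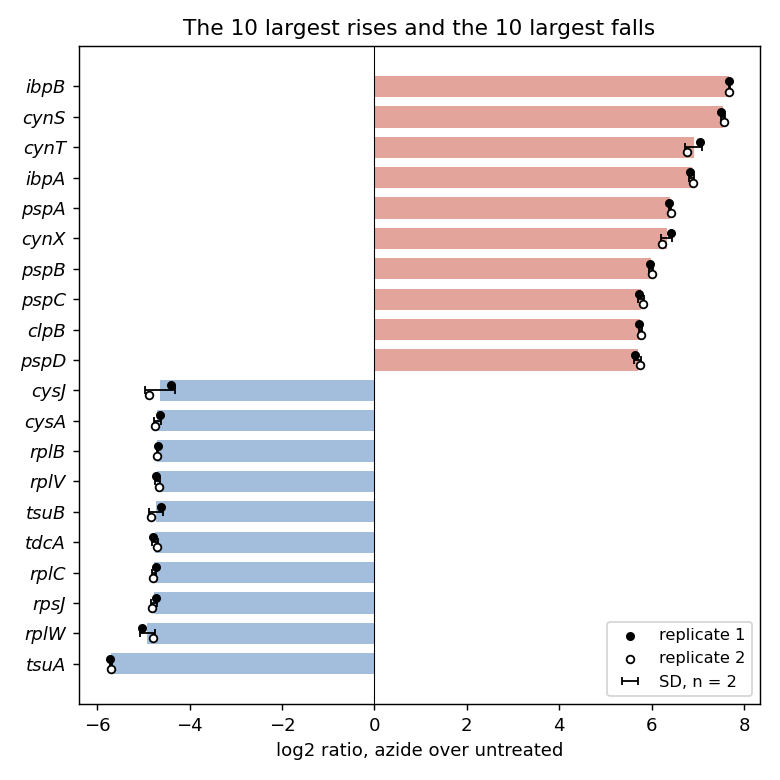
Mean log2 ratio of azide over untreated (x axis) for the 10 genes with the largest rise and the 10 with the largest fall; bars are means, circles the 2 replicate arrays and whiskers the SD. The rises run from 5.70 for pspD to 7.68 for ibpB and the falls from -4.64 for cysJ to -5.71 for tsuA, with the 2 arrays close together for each gene.

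Of 3973 genes tested, 1595 rose, 1573 fell and 805 did not pass the threshold; centring each array on its median in place of loess gave 1896 rises and 1415 falls. At a log2 size of at least 1, 575 of the called genes rose and 575 fell; at a size of at least 3, 92 rose and 54 fell. The smallest called change was 0.15 and the median called change 0.72. Azide carried Cy5 on both arrays, so a rise or fall can hold a dye effect as well as one of azide. Loess sets the bulk of ratios to 0, so the counts are relative to it and the near balance of rises and falls is partly built in. For 79 called genes the fold is only a bound, because a channel was not well above background on either array.

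All 20 genes of the heat shock list, which holds chaperones and proteases, rose, with a median of 2.85 (camera, adjusted p = 9.03e-09; adjusted p = 0.490 with an estimated correlation). Besides ibpB, ibpA and clpB, the largest was the chaperone gene htpG at 5.04 ± 0.01. The chaperone genes dnaK, groS and groL were at 4.88, 4.58 and 4.46, the proteases lon and ftsH at 2.46 and 1.52, and rpoH, the sigma factor gene of the response, rose by 0.44. In the phage shock list 6 of 7 genes rose, with a median of 5.70, and pspF, which encodes the activator of the operon, fell by 0.37. The list passed by camera (adjusted p = 0.00182, and adjusted p = 0.490 with an estimated correlation). The psp operon held 5 of the 7 genes, which are not independent of each other.

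In the list of RpoS-dependent general stress genes all 13 tested genes rose, with a median of 3.15 (adjusted p = 1.93e-06; adjusted p = 0.490 with an estimated correlation). The periplasmic protein gene osmY was at 4.88 ± 0.12, the lipoprotein gene osmE at 3.49 ± 0.07, the transaldolase gene talA at 3.35 ± 0.05 and the pyruvate oxidase gene poxB at 3.33 ± 0.13. Of 16 acid resistance genes, 15 rose and cadC fell, at -0.23, with a median of 3.11 (adjusted p = 1.93e-06; adjusted p = 0.490 with an estimated correlation). The glutamate decarboxylase genes gadB and gadA were at 5.11 ± 0.04 and 4.39 ± 0.20, values that are uncertain as single genes because the sequences are nearly identical. The antiporter gene gadC was at 4.71 ± 0.07 and the lysine decarboxylase gene cadA at 3.90 ± 0.11.

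Of 18 genes of the SOS response to DNA damage, 13 rose, 0 fell and 5 were not called, with a median of 1.16 (adjusted p = 5.65e-04; adjusted p = 0.490 with an estimated correlation). The repair gene recN was at 3.32 ± 0.03, the polymerase gene polB at 3.20 ± 0.01, the gyrase inhibitor gene sbmC at 2.13 ± 0.01 and the polymerase gene dinB at 1.73 ± 0.07. The recombinase gene recA and the repressor gene lexA rose by 1.15 and 1.54, while dinI, dinG, dinD, recX and ruvA lay between -0.07 and 0.13 and were not called.

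All 52 tested ribosomal protein genes fell, with a median of -2.68 and a range from -4.92 for rplW to -1.08 for rpmI (adjusted p = 1.59e-18; adjusted p = 0.490 with an estimated correlation). The 8 cold shock genes fell too, with a median of -2.49 (adjusted p = 4.20e-04; adjusted p = 0.490 with an estimated correlation). Among these, the RNA chaperone gene cspA was at -2.76 ± 0.0028 and its relatives cspG, cspB and cspF were at -3.81 ± 0.06, -3.33 ± 0.03 and -3.08 ± 0.08; the processed signals gave -4.69 for cspF.

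Nucleotide synthesis genes fell as well. All 15 purine genes fell, with a median of -1.90 (adjusted p = 2.93e-06; adjusted p = 0.497 with an estimated correlation). The largest falls were in guaA and guaB of GMP synthesis, at -2.44 ± 0.06 and -2.13 ± 0.10, and in purM and purL, at -2.19 ± 0.28 and -2.14 ± 0.12. In the pyrimidine list 12 of 14 genes fell, pyrF rose by 0.32 and pyrG, at 0.18, was not called; the median was -1.40 (adjusted p = 5.16e-04; adjusted p = 0.490 with an estimated correlation). The uracil salvage genes upp and uraA were at -2.60 ± 0.06 and -2.36 ± 0.19, and pyrD and pyrC at -2.50 ± 0.02 and -2.17 ± 0.08; the processed signals gave -3.92 for uraA, -3.38 for pyrD and -2.78 for purM, and medians of -2.50 for the purine and -2.18 for the pyrimidine list.

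In the list of cysteine synthesis and sulphur assimilation, 14 of 21 tested genes fell, 4 rose and 3 were not called, with a median of -2.90 (adjusted p = 4.27e-04; adjusted p = 0.490 with an estimated correlation). Besides cysA and cysJ, the sulphate transporter genes cysW and cysU were at -4.14 ± 0.08 and -3.80 ± 0.04, with -5.31 for cysW and a list median of -3.55 from the processed signals. The 4 that rose were the serine acetyltransferase gene cysE, at 0.67, and tauA, tauB and tauD of taurine use, at 0.21, 0.32 and 0.15; the processed signals gave 1.28 for tauA.

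**Figure D2:**
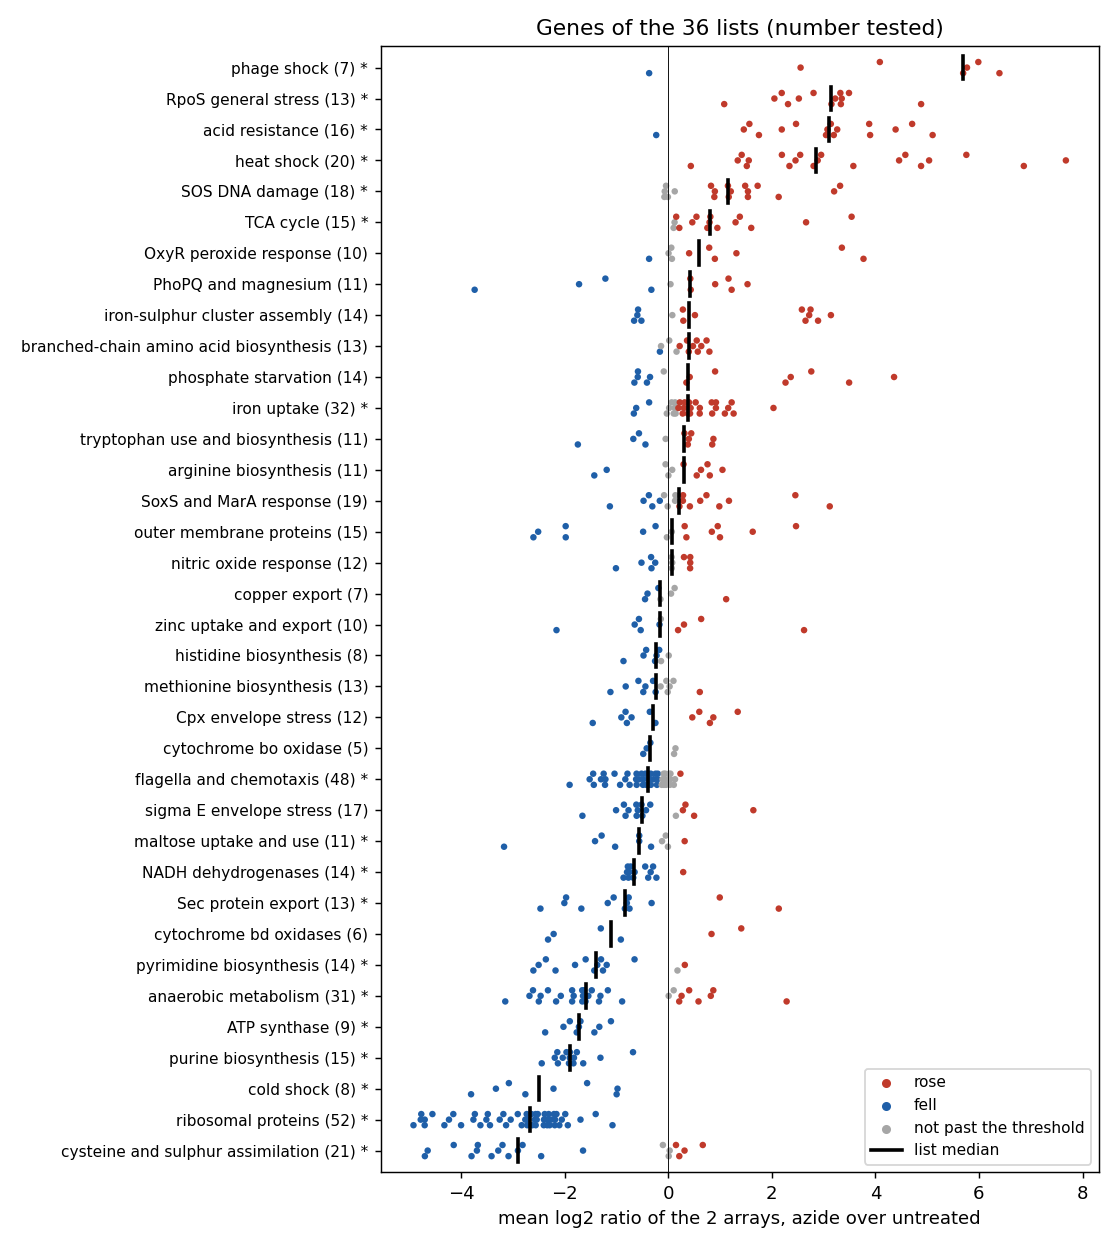
Mean log2 ratio of azide over untreated (x axis) of each tested gene in the 36 lists (y axis, number of tested genes in brackets); red points rose, blue points fell, grey points did not pass the threshold, black bars are list medians and asterisks mark lists past the camera threshold. Medians run from -2.90 for cysteine and sulphur assimilation to 5.70 for phage shock.

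Genes of energy metabolism moved in both directions. All 9 ATP synthase genes fell, with a median of -1.72 (adjusted p = 3.75e-04; adjusted p = 0.490 with an estimated correlation), led by atpG at -2.37 ± 0.13, atpA at -2.02 ± 0.15, atpH at -1.90 ± 0.02 and atpD at -1.77 ± 0.05. Of 14 NADH dehydrogenase genes, the 13 of the proton-pumping nuo complex fell and ndh, of the non-pumping enzyme, rose by 0.29; the median was -0.66 (adjusted p = 0.00537; adjusted p = 0.490 with an estimated correlation). The nuoI, nuoK, nuoM and nuoL genes were at -0.86 ± 0.0047, -0.79 ± 0.13, -0.78 ± 0.01 and -0.77 ± 0.22. Centring each array on its median in place of loess ended the call of this list (adjusted p = 0.0656), though its median there was -0.72. The 9 ATP synthase genes lie in a single operon and the 13 nuo genes in another. Genes of an operon are not independent, which the preset correlation of 0.01 hardly allows for.

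In the tricarboxylic acid cycle 13 of 15 genes rose, while fumA and sucB, at 0.12 and 0.10, were not called; the median was 0.80 (adjusted p = 6.10e-04; adjusted p = 0.490 with an estimated correlation). The aconitase gene acnA was at 3.54 ± 0.07, the citrate synthase gene gltA at 2.66 ± 0.13, and sdhC and sdhD of succinate dehydrogenase at 1.60 ± 0.06 and 1.38 ± 0.11. Of 31 tested genes of anaerobic metabolism, 22 fell, 7 rose and 2 were not called, with a median of -1.60 (adjusted p = 5.65e-04; adjusted p = 0.497 with an estimated correlation). The hydrogenase gene hybO was at -3.15 ± 0.13, the dicarboxylate carrier gene dcuC at -2.68 ± 0.05, the dimethyl sulphoxide reductase gene dmsA at -2.61 ± 0.15 and the asparaginase gene ansB at -2.50 ± 0.02. The lactate dehydrogenase gene ldhA went the other way, at 2.29. The processed signals gave -3.98 for dcuC.

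The Sec protein export list, which bears on a known target of azide, held members going both ways. The motor gene secA rose by 2.14 ± 0.06 (SD, n = 2; adjusted p = 3.05e-09) and secM, which lies before it and regulates its translation, by 1.00 ± 0.06 (adjusted p = 5.02e-07). The other 11 of the 13 genes fell. The largest falls were in the insertase gene yidC at -2.47 ± 0.0016 and the channel genes secY, which fell 4.01-fold, and secG at -1.97 ± 0.13. The secY gene was the last of those examined in the spc operon, which also holds ribosomal protein genes and had a median of -2.52. Its fall cannot be told apart from theirs. The operons of yidC and secG were not examined. The list median was -0.84 (adjusted p = 0.00954; adjusted p = 0.490 with an estimated correlation).

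In the iron uptake list 22 of 32 tested genes rose, 3 fell and 7 were not called, with a median of 0.38 (adjusted p = 0.00329; adjusted p = 0.490 with an estimated correlation). The siderophore reductase gene fhuF was at 2.03 ± 0.08, and the ferric citrate transport genes fecA, fecB and fecC were at 1.26 ± 0.10, 1.23 ± 0.10 and 1.16 ± 0.16; the processed signals gave 2.93 for fhuF and 2.09 for fecC. The ferrous iron genes feoA and feoB and the energy-coupling gene exbB were the 3 that fell, at -0.62, -0.37 and -0.66, with -1.29 for exbB from the processed signals. Median centring ended the call of the list (adjusted p = 0.0689), though its median there was 0.53. The processed signals gave a list median of 0.93. Counted among the rises were fiu, entE and fepD, at 0.28, 0.30 and 0.32. Their untreated channel was not well above background on either array, so these are not measured folds. The same held for entC and entB among the genes not called.

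Of 48 tested genes of flagella and chemotaxis, 33 fell, cheZ rose by 0.24 and 14 were not called, with a median of -0.38 (adjusted p = 3.75e-04; adjusted p = 0.490 with an estimated correlation). The basal body and switch genes flgC, fliM and flgG were at -1.90 ± 0.0014, -1.45 ± 0.17 and -1.44 ± 0.01. The hook gene flgD was fitted 2.86-fold lower, but was not well above background with azide on either array. Its bound equals the fitted mean and sets no firm lower limit. The processed signals gave -4.19 for flgC, -2.32 for fliM and -2.20 for flgG, and a list median of -1.28. For flgD they gave -4.86, which is not a measured fold. In the maltose list 7 of 11 genes fell, lamB rose by 0.32 and 3 were not called, with a median of -0.56 (adjusted p = 0.0405; adjusted p = 0.497 with an estimated correlation). The transport gene malK was at -3.17 ± 0.12, malF at -1.41 ± 0.01, malM at -1.28 ± 0.09 and malG at -1.02 ± 0.13. An offset of 0 ended the call of this list (adjusted p = 0.0691), with a median of -0.52.

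The other 18 lists did not pass the threshold. For the OxyR peroxide response the adjusted p was 0.0540, with a median of 0.60; 6 of 10 genes rose, among them the iron-storage gene dps at 3.77 and the catalase gene katG at 0.40 ± 0.05, and 5 of the alternatives placed the list past the threshold by camera. Iron-sulphur cluster assembly had a median of 0.40 (adjusted p = 0.0893), with sufA, sufB, sufC, sufD, sufS and sufE between 2.58 and 3.14 and iscX, hscA, hscB and fdx between -0.66 and -0.52; the processed signals gave 3.81 for sufA, 3.49 for sufB, 3.44 for sufC, 3.31 for sufE and 3.30 for sufD. Branched-chain amino acid synthesis had a median of 0.40 (adjusted p = 0.0646) with 9 of 13 genes rising, and sigma E envelope stress a median of -0.51 (adjusted p = 0.0893) with 12 of 17 falling. Phosphate starvation had a median of 0.38 (adjusted p = 0.236), with phoH at 4.36 and ugpB, of glycerophosphate uptake, at 3.49, or 5.89 and 4.68 with the processed signals. Cytochrome bd oxidases had a median of -1.11 (adjusted p = 0.321): cydA fell by 2.21 ± 0.07 (SD, n = 2; limma's adjusted p = 2.67e-09) and cydB by 2.32, while appB and appC of the alternative oxidase rose by 1.41 and 0.84.

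In the SoxS and MarA list the median was 0.22 (adjusted p = 0.227), with the superoxide dismutase gene sodA at 3.12 and soxS at 2.46. The medians were -0.24 for histidine (adjusted p = 0.116), -0.24 for methionine (adjusted p = 0.183) and 0.30 for arginine synthesis (adjusted p = 0.359), where argF, nearly identical to argI, is uncertain. The cytochrome bo oxidase list was at -0.34 (adjusted p = 0.521); 3 of its 5 genes fell, and cyoA, at 0.14 ± 0.03, missed the threshold (adjusted p = 0.0596). The Cpx envelope stress list was at -0.30 (adjusted p = 0.695) and zinc uptake and export at -0.15 (adjusted p = 0.697). The sign of the median, the mean and the test differed for PhoPQ and magnesium (median 0.43, adjusted p = 0.690), tryptophan use (0.31, 0.772), outer membrane proteins (0.07, 0.919), nitric oxide response (0.07, 0.919) and copper export (-0.15, 0.772; 0.01 under median centring). Adjusted over the list alone, the numbers of rises and falls were the same in 34 of the 36 lists; sigma E envelope stress then held 5 rises in place of 4 and zinc uptake and export 6 falls in place of 5.

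Genes deleted in BW25113 served as a control for the arrays. The araB, araA, araD, rhaB, rhaA and rhaD probes were not well above background in either channel on either array. For lacZ, whose probe was not placed within or outside the deleted part, the untreated channel was not well above background on either array and the azide channel was on both. Its ratio is therefore only a bound. That bound, 0.01 on the log2 scale, equals the fitted mean of 0.15 and -0.14 on the 2 arrays and sets no firm lower limit. A test against a channel at background decides nothing. Ratios against that channel passed the threshold with the processed signals (1.38), the series value table (1.37) and no background subtraction (0.20), and none of these is a measured fold.

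Across the 3973 genes the log2 ratios of the 2 arrays correlated at r = 0.993 and rho = 0.982, which describes the arrays only, since genes are not independent replicates. The median SD between the arrays was 0.07, and 302 genes had opposite signs on the arrays, 0 of them called. The spike-in ratios followed their nominal values with slopes of 0.814 and 0.860 on the arrays of replicates 1 and 2, the first outside the range the scanner software accepts.

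**Figure D3:**
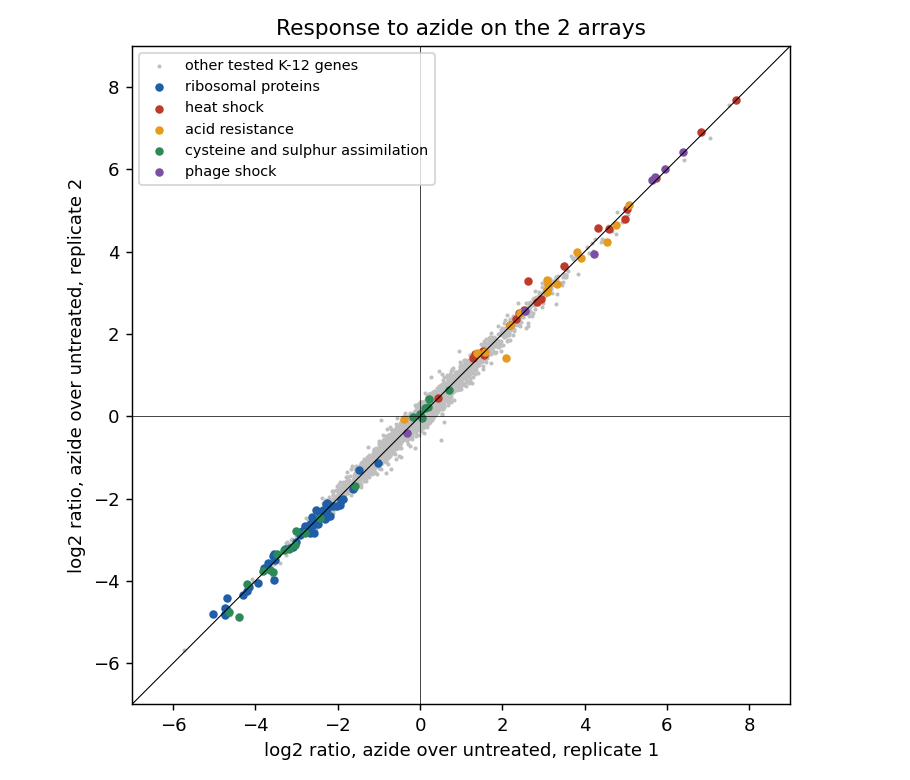
Log2 ratio of azide over untreated on the array of replicate 1 (x axis) against that of replicate 2 (y axis), each point a tested gene, with genes of 5 lists coloured and the line of equality drawn. The genes lie along the line (r = 0.993), ribosomal protein and sulphur genes mostly at the lower left and heat shock, acid resistance and phage shock genes mostly at the upper right.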

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

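The spots without a K-12 locus tag were counted after the data had been seen, and no explanation was tested. The array carried 7059 such non-control spots. They entered the comparisons of genes and lists only under the alternative with all genes named on the array, and were not excluded from the checks on spots of the slide. Of these, 29.6% (2086 spots) were well above background in both channels on both arrays, against 0 of 3791 negative control spots and 88.2% of the K-12 spots. By the prefix of their names the share was 35.1% for c, 25.3% for ECs and 27.7% for Z. The log2 ratios of these bright spots correlated between the arrays at r = 0.991 across spots.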

How the results depend on the processing

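No test in this part was chosen after its result was seen. The analysis is itself paired, since each array's ratio pairs the portions of 1 culture, so no further paired analysis was added. The numbers of rises and falls stayed within 1.5 times of 1595 and 1573 under the alternatives, except that using all genes named on the array gave 2367 falls, from more genes tested, and a required log2 size of at least 1 left 575 rises and 575 falls by construction. Of the 3168 calls, 3021 kept their sign and call with the scanner's processed signals, 2995 under median centring and 3070 with an offset of 0, where 1 called gene turned sign. Genes at least 2-fold higher on average numbered 895 with the processed signals and 887 with the series value table, against 575. Those at least 2-fold lower numbered 836 and 845, also against 575. Log2 ratios under these settings were steeper, with a slope of 1.21 on those reported. Leaving out a replicate gave 570 to 572 genes at least 2-fold higher and 563 to 590 lower, with no test, since no residual degrees of freedom remain. Of the 36 list medians, 9 moved by over 1 SD between the arrays without replicate 1 and 10 without replicate 2. The largest move of a list median was 0.13, and 0 changed sign. A plain mean of 2 arrays always moves by less than 1 SD when 1 is left out. A list median is taken over gene means, and can move further only where it lies off the midpoint of the medians of the 2 arrays. The counts are therefore no measure of robustness. The correlation of the arrays was 0.983 with the processed signals, 0.983 with the series value table, 0.985 with an offset of 0, 0.993 for genes well above background in both channels and 0.992 with all genes named.

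The list calls were made with the preset correlation of 0.01, while mean log2 ratios of neighbouring genes correlated at 0.518. Genes of an operon are therefore not independent. The calls of ATP synthase, NADH dehydrogenases and phage shock, made largely of a single operon each, rest on fewer independent units than genes. With an estimated correlation, on 1 residual degree of freedom, 0 lists were higher and 0 lower. For the called lists camera's adjusted p was then 0.490 to 0.497, whatever the estimate. The estimate was below the preset 0.01 for ribosomal proteins (-0.018) and ATP synthase (-0.111). It was above 0.01 for heat shock (0.116) and purine biosynthesis (0.314). The size of the correlation does not account for the loss where the estimate was lower, so this setting cannot decide the calls. By fry, which does not compare a list with other genes, 12 lists were higher and 17 lower, and outer membrane proteins reversed (median 0.070, adjusted p = 0.00935); the cause was not tested. Median centring moved the median of all tested genes from 0.02 to 0.12; it ended the calls of iron uptake (median 0.53, from 0.38) and NADH dehydrogenases (-0.72, from -0.66) and placed iron-sulphur cluster assembly (0.35, from 0.40), phosphate starvation (0.53, from 0.38) and the OxyR list (0.56, from 0.60) past the threshold. Calls thus did not always follow the sizes of the medians, and the cause was not tested. Over the 12 other processing settings, camera's adjusted p ran from 7.72e-04 to 0.0689 for iron uptake, 0.00390 to 0.0656 for NADH dehydrogenases, 0.0336 to 0.0691 for maltose, 0.0106 to 0.104 for iron-sulphur cluster assembly and 0.00900 to 0.366 for phosphate starvation. For OxyR it ran from 0.0376 to 0.0659, past the threshold in 5 settings. The cyoA gene passed with an offset of 0 (0.30) and with no background subtraction (0.17; limma's adjusted p from 0.0149 to 0.277 over the settings). For lacZ, whose untreated channel was at background, it ran from 0.00215 to 0.956, which decides nothing. Some genes gave convergence warnings in the separate-channel fit. The variance model does not enter the correlation of the arrays, so it gave no value there. Signal over background limits dim genes, whose ratios the offset compresses.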

Other observations

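The 16 gene lists here were drawn up after the data had been seen, 5 of them (cyanate, arginine degradation, glycolate, threonine degradation and ycgZ to ymgC) because of their values, and the test of order within operons was also chosen after its result was seen. A list test on those 5 decides nothing, so they are described without one. Of the 11 others 0 were higher, 4 lower and 7 not called by camera, adjusted over the 11 lists. With an estimated correlation 0 were called, and the adjusted p of the 4 lower lists was 0.537 to 0.599. That setting has 1 residual degree of freedom and cannot decide these calls, which were made only with the preset correlation.

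Genes of translation other than ribosomal proteins fell too. All 14 translation factor genes fell, with a median of -1.59 (adjusted p = 2.45e-05; adjusted p = 0.537 with an estimated correlation), among them the elongation factor gene tsf at -2.42 and the initiation factor gene infA at -2.46; tufA and tufB, at -1.75 and -1.54, are nearly identical and uncertain as single genes. Of 22 aminoacyl-tRNA synthetase genes 20 fell, with a median of -1.07 (adjusted p = 2.45e-05; adjusted p = 0.537 with an estimated correlation), while ileS and valS, at 0.07 and 0.05, were not called. Both lists had been predicted to fall before their values were seen, but after the fall of the ribosomal protein genes was known. Both fell as predicted. The fusA and tufA genes lie in the str operon, which also holds ribosomal protein genes and had a median of -1.90. Whether other factor genes, such as tsf, share operons with ribosomal protein genes was not examined. The factor list is therefore not independent of the fall of the ribosomal protein genes. Fatty acid synthesis fell in 12 of 12 genes, with a median of -1.12 (adjusted p = 1.86e-04; adjusted p = 0.537 with an estimated correlation), and lipopolysaccharide synthesis in 10 of 11, with a median of -0.78 (adjusted p = 0.0233; adjusted p = 0.599 with an estimated correlation), lpxC rising by 0.82.

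Of the lists chosen for their values, cyanate use rose in 4 of 4 genes, with a median of 6.61, and the 6 tested threonine degradation genes fell, with a median of -2.79. The arginine degradation genes rose in 5 of 5 cases with a median of 3.14, led by astC at 4.60. The glycolate genes rose in 5 of 5 with a median rise of 8.55-fold, and the 4 genes from ycgZ to ymgC, of a biofilm and acid resistance locus, with a median of 4.70. The processed signals gave 6.21 for astC and medians of 7.67 for cyanate use, 4.67 for arginine degradation, 5.85 for ycgZ to ymgC and -3.68 for threonine degradation. The lists not called were RNA polymerase (median -0.91, adjusted p = 0.179), where rpoD rose by 1.37 and the 4 core genes fell, peptidoglycan and cell division (0.26, 0.138), fatty acid degradation (0.37; past the threshold only before adjustment), glycolysis (0.31, 0.140), the sugar phosphotransferase system (-0.26, 0.535), glyoxylate and gluconeogenesis (-0.02, 0.943; 0.05 with the processed signals) and toxin-antitoxin pairs (0.29, 0.204).

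The fall of ribosomal protein genes and the rise of heat shock genes were set against artefacts of the arrays. For a bias with spot intensity left after loess, each list was set against 10000 random lists matched on intensity. Their medians went no lower than -0.806 for ribosomal proteins and no higher than 1.46 for heat shock, against -2.68 and 2.85. Other genes of like intensity thus did not share the shifts. Loess centres the ratios at each intensity, so typical matched medians near 0 (0.128 and -0.178) were largely built in, and the check is weak. Regions of the slide reading low or high together were argued against, as bright spots beside the list's spots had medians of 0.026 for ribosomal protein genes and -0.029 for heat shock genes. For a single gene dye bias cannot be told apart from treatment, since 0 arrays had the dyes swapped. A dye bias unrelated to gene function would also have shifted random lists. Loess does not build in the spread of their medians, yet none of the 10000 went beyond -0.806 or 1.46. That argues against such a bias as the source of the shifts to -2.68 and 2.85. A dye bias shared by the probes of a list stays open. An effect of azide stays a hypothesis beside that shared bias.

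The close agreement of the 2 arrays was also examined. A single hybridisation deposited more than once is argued against, since probe means differed between the arrays with 7.07 times the variance that replicate spots give (95% of resampled values from 2.80 to 12.5). The same RNA labelled more than once could be a source of the agreement. With mean response and intensity removed, differences between the arrays correlated at only 0.048 across neighbouring genes (permutation p = 0.00600). This is above chance but below the bound of 0.1 set beforehand, so the question stays open. Without that removal the differences correlated at 0.051 across neighbouring genes and at 0.057 across neighbouring spots of the slide. For comparison, the mean log2 ratios of neighbouring genes correlated at 0.518.

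A candidate explanation for uneven falls within operons is that genes near the promoter fall first. Over 14 operons the mean Spearman rho of log2 ratio with position was 0.070 (two-sided permutation p = 0.592), with 7 operons above 0. Over the 12 operons whose median fell below 0, which the hypothesis concerns, it was 0.238, with 7 above 0, and missed the threshold (two-sided permutation p = 0.0901). The value over all 14 met the bound of under 0.1 first set against the hypothesis; after it was seen, the bound was made to include the spread of the permuted means (SD 0.128), which leaves the question open.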
